A study of Mus musculus with 4 samples.

How the data were processed

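RNA of sorted LTi cells of C57BL/6 mice was extracted with a Qiagen miRNeasy Micro kit and made into libraries with Smart-seq2, a full-length cDNA method without molecular identifiers, per the labels' protocols. Reads were processed with Subread and featureCounts against the mouse build mm10, per the submitters' processing notes. Versions, the annotation release and the handling of reads with several positions are not given in the sources used here. The deposited table holds 27179 genes by Entrez identifier and 1 column per library. The deposited values are log2(RPKM + 1) with 0.0001 added, which was worked out from the values themselves, so a gene without reads is listed at 0.0001. Each library is scaled to its own total only.

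The main test had been planned on counts, and the table holds none, so the fallback fixed before the data were examined was used: limma 3.58.1 in R 4.3.3 with trend and robust variance, on log2(RPKM + 1) as deposited (pseudocount 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. Of tests on counts only limma-voom was run, as an alternative and on reads recovered as described below. Scaling by library size alone, which was also planned, is the deposited scale itself.

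Whole reads were recovered from the values, since those of a gene are whole multiples of what a single read is worth in each library. In 99.99% of genes with reads, all 4 read numbers came out whole within 0.001 reads, and recovered reads made up 98.9%, 99.1%, 98.8% and 98.6% of the totals of control replicates 1 and 2 and VavCre replicates 1 and 2. They served for the depth, the filter and scaling. Recovery was tested on simulated data of 18601 genes, where all 4 library totals and 96.4% of genes were recovered exactly. Gene lengths were chosen to make the read numbers whole and were reused in the simulation, so neither share shows that each length was right. The VavCre libraries were 1.79 times as deep as the control libraries on average. A floor of 3 reads was 0.210, 0.237, 0.123 and 0.125 CPM in the same order. Intervals and floors cover counting error only.

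Genes entered the test with at least 0.5226 CPM in at least 2 libraries and 15 reads in total, 14285 genes. Symbols and GRCm38.p6 coordinates came from RefSeq, in which 25275 of the identifiers were found. The model was tested on simulated data for this comparison, with 200 of 14285 genes changed in each of 5 draws. On the deposited scale it called 14.8% of genes changed 2-fold, 88.4% of those changed 4-fold, 98.4% at 8-fold and 100% at 16-fold, and 7.61% of its calls were false. After median-ratio scaling it called 16% at 2-fold and 87.2% at 4-fold, with 6.91% false calls. The simulated genes shared the same dispersion (0.0506), were changed up or down at random and had no shift of the median gene. In the real libraries the median gene lay 0.43 log2 units higher in VavCre on the deposited scale, so these rates do not carry over to the calls made there.

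The named genes were fixed by rule before the data were examined. They are Gata3 and the genes of the sort gate, up to 12 higher and 12 lower called genes by log2 difference, up to 4 called genes per list by adjusted p, and 20 genes of LTi cells whatever their result. The genes ranked by log2 difference needed 10 CPM in the higher group and genotypes that did not overlap, and predicted genes, pseudogenes and genes of the immunoglobulin and T cell receptor loci were left out. Some genes that meet the rule are not reported here, and their places were not refilled. Iltifb, H2-DMb1, Rgs2, Muc2, Cd3d, Trdc, Slc29a3 and Igha were named after their values were seen. The gene lists were fixed before the data were examined too, and include markers of T cells, B and plasma cells, myeloid cells, epithelium and stroma. Lists with at least 5 tested genes were tested with camera in limma (preset correlation 0.01), of which 15 of 23 were called, and none with an estimated correlation. That correlation was estimated from only 4 libraries, which left camera little power (smallest adjusted p = 0.42 over the 23 lists). A call missing there is therefore no evidence that a list did not shift. Members were also counted after adjustment over the list alone.

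The alternatives were median-ratio, upper-quartile and TMM scaling, no filter, a filter of 5 CPM, limma-voom on recovered reads, a pseudocount of 0.1, a replicate block, a fold threshold of 1.5 and leaving out each library. TMM scaling and the combinations of median-ratio scaling with voom, the block and left-out libraries were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.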

Results

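Gene expression was measured by RNA sequencing in lymphoid tissue inducer (LTi) cells, innate lymphoid cells that make lymphotoxin, sorted from the lamina propria of the mouse small intestine. The sort kept live lineage-negative cells that carried CD127 and CCR6 and lacked KLRG1, NK1.1 and NKp46. There were 4 libraries, 2 from Gata3+/+ mice (control) and 2 from Gata3fl/fl mice with the VavCre transgene (VavCre), in which Cre is made in blood cells and floxed Gata3, a transcription factor of T cells and innate lymphoid cells, can be deleted. The control libraries held 14294708 and 12670034 reads and the VavCre libraries 24315878 and 23973995 reads. The study's title asks about innate lymphoid cells, B cell residency and IgA switching in the gut, and the comparison reported here is of LTi cells with and without floxed Gata3.

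Gata3 (Entrez 14462, chromosome 2: 9857078 to 9887953, GRCm38) was measured at 84.3 and 50.7 RPKM in the control libraries and at 34.5 and 23.3 RPKM in the VavCre libraries. The means were 67.5 ± 23.7 and 28.9 ± 7.91 RPKM (SD, n = 2 per genotype), and both VavCre libraries lay below both control libraries. The log2 difference of −1.18 ± 0.36 (SE) had an adjusted p of 0.0907 in limma, so Gata3 did not pass the test. The values cover the whole gene, and a conditional deletion can leave some exons transcribed, so they check the labels only in part.

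Il22 and Arg1 fell and Il17a rose in the VavCre libraries. Il22, a cytokine that acts on epithelium (Entrez 50929, chromosome 10: 118204584 to 118210047), stood at 1960 ± 623 RPKM in control and 208 ± 112 RPKM in VavCre cells (SD, n = 2), a 9.44-fold difference of the means. Arg1, which codes for arginase 1 (chromosome 10: 24915207 to 24927470), fell from 218 ± 80.6 to 6.57 ± 1.94 RPKM. Cd4 fell from 44.8 ± 11.7 to 10.5 ± 2.45 RPKM, and Il17a, the interleukin 17A gene (chromosome 1: 20730905 to 20734496), rose from 11.9 ± 4.05 to 121 ± 0.713 RPKM. In limma the log2 differences were −3.31 ± 0.48 for Il22 (adjusted p = 0.0214), −4.83 ± 0.36 for Arg1 (adjusted p = 0.00717), −1.98 ± 0.32 for Cd4 (adjusted p = 0.0259) and 3.28 ± 0.31 for Il17a (adjusted p = 0.0112). Reads of Il22 can be shared with Iltifb, its near-identical copy, whose own values of 53.4 and 36.0 RPKM in control and 3.11 and 6.80 RPKM in VavCre libraries are therefore uncertain.

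Ret and Klrk1, which code for receptors, were among the other genes with large falls. Ret, the receptor for glial-derived neurotrophic ligands, fell from 55.1 ± 25.8 to 0.986 ± 0.293 RPKM, and Klrk1, the activating receptor NKG2D, from 23.2 ± 2.60 to 0.503 ± 0.0305 RPKM. Ncr1, which codes for the NKp46 that the sort selected against, was at 6.84 and 14.8 RPKM in control and 0.0562 and 0.428 RPKM in VavCre libraries. The log2 differences were −4.75 for Ret, −4.01 for Klrk1, −3.18 for Ncr1, −5.28 for Ccdc184, −4.44 for Fam184b, −3.68 for Adgrg3, −3.54 for Upp1 (uridine phosphorylase), −3.46 for Epas1 (the hypoxia-inducible factor HIF-2α), −3.33 for Hs6st2, −3.31 for Pxdc1 and −3.18 for Eng (endoglin). All of these passed limma's test on the deposited scale, and after median-ratio scaling all but Ncr1 (adjusted p = 0.0535) and Epas1 (adjusted p = 0.0574) passed it too. Without VavCre replicate 1 and without VavCre replicate 2 the log2 differences were −2.88 and −4.19 for Upp1 and −2.57 and −4.35 for Epas1, and without control replicate 1 and without control replicate 2 they were −4.70 and −5.87 for Ccdc184 and −2.67 and −3.99 for Hs6st2.

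**Figure D1:**
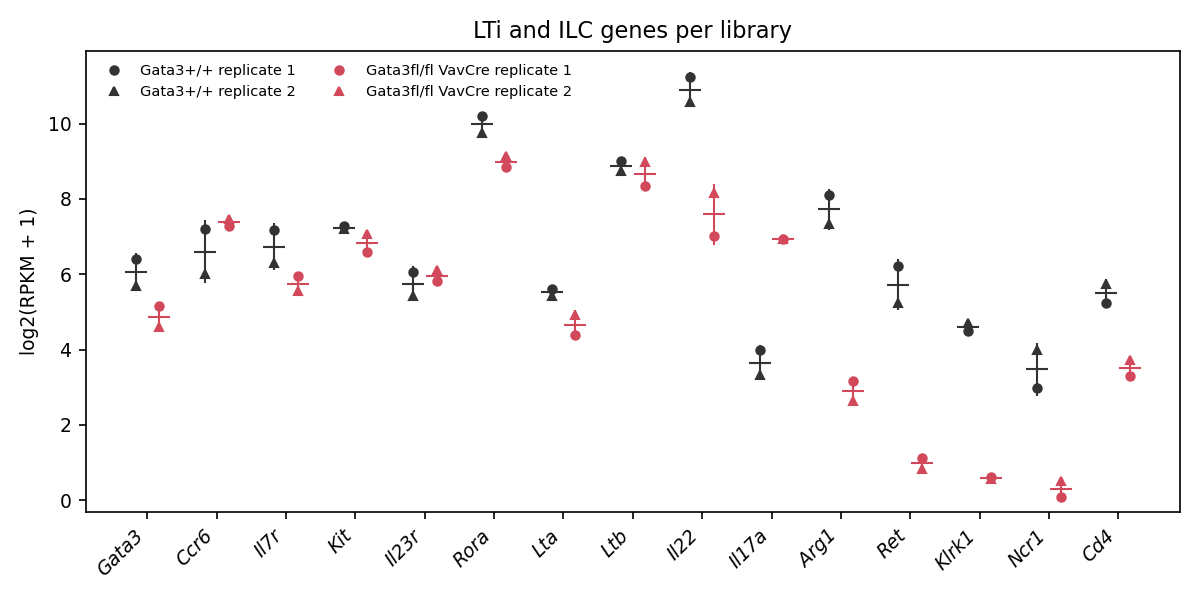
Expression of LTi and other innate lymphoid genes as log2(RPKM + 1) in each library, with circles for replicate 1, triangles for replicate 2, horizontal bars for the mean and vertical lines for the SD of the 2 libraries of a genotype. Il22 stood at 2401 and 1520 RPKM in control against 129 and 287 RPKM in VavCre libraries, whereas Il17a stood at 14.8 and 9.03 RPKM in control against 121 and 122 RPKM.

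Most LTi genes fixed in advance did not pass the test. The log2 differences were −0.99 for Rora, −1.97 for Tbx21, −0.35 for Id2, 0.45 for Tcf7, −0.41 for Kit, 0.13 for Cxcr5, 0.72 for Il1r1, 0.22 for Il23r, 0.13 for Il2ra and 0.06 for Ahr. Of those, Tcf7, Cxcr5, Il23r, Il2ra and Ahr turned negative with median-ratio scaling, while Rora lay at −1.59 and Id2 at −0.95, and Rora passed with limma-voom and that scaling (adjusted p = 0.0466) but not with limma on log2 RPKM (adjusted p = 0.0577). Tbx21 varied widely within genotypes, at 6.22 and 29.3 RPKM in control and 7.96 and 0.588 RPKM in VavCre libraries, and the genotypes overlapped. Among ligands, Lta differed by −0.86, Ltb by −0.20, Tnfsf11 (RANKL) by −0.44, Tnfsf13b (BAFF) by −0.28, Tnfsf13 (APRIL) by 0.39, Il17f by −0.46 and Csf2 by −1.57 (adjusted p = 0.0566 in limma), none of which passed. Tnfsf13b had only 0 and 42 reads in control and 0 and 15 in VavCre libraries. Tnfsf13 had 17 and 2 reads in control and 24 and 41 in VavCre libraries. These are too few to tell whether either gene changed. After median-ratio scaling Lta lay at −1.44, Ltb at −0.80, Tnfsf11 at −1.04 and Csf2 at −2.11, none of which passed in limma, and on the deposited scale Csf2 passed with the stricter filter (adjusted p = 0.0298 in limma). The genes of the sort gate other than Ncr1 did not pass either, with log2 differences of −0.98 for Il7r, 0.77 for Ccr6, −0.52 for Klrg1 and 1.13 for Klrb1c.

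Camera (limma) with its preset correlation placed the lists of LTi identity, ILC3 cytokine, ILC2 and ILC1 genes below the other genes. It did not call the lineage transcription factors. With an estimated correlation, a setting with little power on 4 libraries, none of those lists kept its call. The median tested gene was 0.43 log2 units higher in the VavCre libraries on the deposited scale, and list medians are given relative to it. The list of LTi and ILC3 identity genes lay at −0.42, with 1 of 25 tested members called higher (Il17a) and 2 lower (Il22, Cd4), and its median was 0.01 on the deposited scale where its mean was −0.16. After median-ratio scaling 15 of the 25 were lower in both VavCre than in both control libraries and 2 were higher, against 25.5% and 29.8% of all tested genes. The ILC3 cytokines and ligands lay at −0.64, with Tnfsf4 and Il17a higher and Il22 lower among 19, and on the deposited scale its median was −0.20 and its mean 0.07. The ILC2 list lay at −0.90, with Areg and Bcl11b higher and Arg1 and Ccr8 lower among 15. The list of ILC1, NK and NKp46+ ILC3 genes lay at −0.42, with Ncr1 and Klrk1 lower and none higher among 28. The adjusted p in camera (limma) were 0.0001, 0.00166, 0.000386 and 3.19e-05 in that order, and each had adjusted p = 0.42 with an estimated correlation. After median-ratio scaling Il17a, Il22, Cd4, Arg1 and Klrk1 still passed and the other called members of these lists did not. Adjusted over the list alone, 1 member was higher and 2 lower in the identity list, 2 and 3 in the cytokine list, 3 and 4 in the ILC2 list and 0 and 2 in the ILC1 list.

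Genes of B cells, plasma cells and epithelium rose in the VavCre libraries. Cd79a, a chain of the B cell receptor complex, rose from 12.4 ± 8.01 to 154 ± 19.4 RPKM, Ighm from 28.4 ± 15.9 to 850 ± 299 RPKM, Epcam, an epithelial adhesion molecule, from 21.1 ± 0.850 to 149 ± 19.4 RPKM and Olfm4, made in intestinal crypts, from 8.60 ± 1.35 to 167 ± 19.9 RPKM. Of the 23 tested B and plasma cell markers, 18 rose, among them Blnk and Fcer2a, and 15 of the 27 tested epithelial markers rose, among them Cdh1 and Elf3, and none fell in either list. Adjusted over the list alone, 21 and 17 rose. The list medians lay 2.53 and 2.04 above the median gene, with adjusted p of 4.45e-09 and 2.01e-07 in camera (limma) and adjusted p = 0.42 and adjusted p = 0.495 with an estimated correlation. After median-ratio scaling only 1 B cell marker (Ighm) and 6 epithelial markers, Epcam, Cdh1, Olfm4 and Elf3 among them, still passed, and among the tested markers of both lists only Muc2, which had not passed, changed sign, from 0.37 to −0.19.

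Some T cell and antigen presentation genes rose too. Cd3g, a chain of the T cell receptor complex, stood at 4.65 and 5.63 RPKM in control and 203 and 53.1 RPKM in VavCre libraries, and 8 of 23 T cell markers rose, with Cd247, Trgc4 and Cd8b1 among them (9 higher and 1 lower adjusted over the list alone). Among 16 genes of MHC class II presentation, 9 rose (13 adjusted over the list alone), including H2-DMb2 (log2 3.60), H2-Ob (3.41), H2-DMa (2.02) and Ifi30 (1.97), although H2-DMb1 and H2-DMb2 are near-identical and can share reads. The list medians lay 1.37 and 1.40 above the median gene, with adjusted p of 0.0458 and 1.36e-05 in camera (limma), and adjusted p = 0.571 and adjusted p = 0.42 with an estimated correlation. B cell, epithelial and some T cell markers rose in the same libraries as the class II genes. Without VavCre replicate 1 the T cell list median lay 0.42 above the median gene, against 1.37 with all libraries. After median-ratio scaling H2-DMb2 passed (adjusted p = 0.0498 in limma) and the other class II genes and all T cell markers, Cd3g included, did not. The T cell list was not called by camera (limma) without control replicate 1, control replicate 2 or VavCre replicate 1, with adjusted p of 0.2, 0.253 and 0.653, and without VavCre replicate 1 and VavCre replicate 2 Cd3g lay at 3.14 and 5.05.

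**Figure D2:**
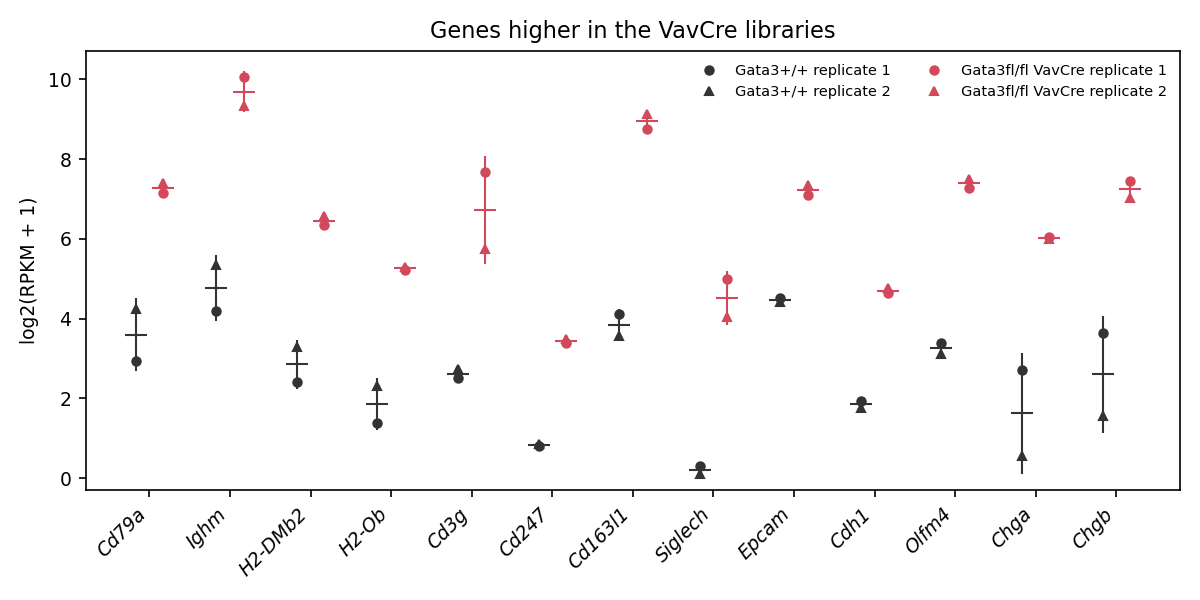
Expression as log2(RPKM + 1) in each library of genes called higher in the VavCre libraries, with circles for replicate 1, triangles for replicate 2, horizontal bars for the mean and vertical lines for the SD of the 2 libraries of a genotype. Cd79a stood at 6.70 and 18.0 RPKM in control and 140.4 and 168 RPKM in VavCre libraries, and Cd3g at 203 and 53.1 RPKM in the VavCre libraries.

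Of the genes with the largest rises, several are expressed by cell types other than LTi cells. Cd163l1, a scavenger receptor, rose from 13.6 ± 3.98 to 497 ± 91.0 RPKM and Ly6d, a surface protein of the early B lineage, from 11.6 ± 8.20 to 352 ± 2.21 RPKM. Chga and Chgb, the chromogranins of secretory granules, rose by 4.40 and 4.64 log2 units, Siglech, a receptor of plasmacytoid dendritic cells, by 4.31, Nuak2 by 4.08 and Fcmr, the receptor for IgM, by 4.01, and the transcription factor gene Spib rose too. Each passed limma's test on the deposited scale, and Cd163l1, Ly6d, Siglech and Nuak2 passed it after median-ratio scaling. Without control replicate 1 and without control replicate 2 the log2 differences were 5.47 and 3.32 for Chga, 5.67 and 3.60 for Chgb, 2.82 and 5.20 for Fcmr, 4.27 and 5.71 for Ly6d and 3.24 and 4.76 for Spib.

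Some metabolic, cell cycle and interferon genes rose, in the same libraries in which B cell, epithelial and some T cell markers rose. Of 75 tested oxidative phosphorylation genes 12 rose, including Ndufv2 (log2 1.76), and 37 adjusted over the list alone. Of 54 cell cycle genes 10 rose, including Birc5 and Aurkb, and 21 adjusted over the list alone. Of 23 cholesterol synthesis genes 6 rose, including Fdft1 (2.10) and Insig1 (1.65), with 14 higher and 1 lower adjusted over the list alone. Of 47 interferon response genes 11 rose, including Ifi27l2a (4.12), Ly6a and Xaf1, and 17 adjusted over the list alone. Camera (limma) placed the lists above other genes with adjusted p of 4.45e-06, 0.00266, 0.00307 and 0.0083, and adjusted p = 0.514 for oxidative phosphorylation and adjusted p = 0.42 for the others with an estimated correlation. None of the members of those 4 lists passed after median-ratio scaling.

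The immediate early genes that rise during tissue dissociation lay −0.62 from the median gene, with Dusp2, Klf6, Myc and Egr2 higher and Rgs2 lower among 42 tested (5 and 2 adjusted over the list alone), and on the deposited scale their median was −0.18 and their mean 0.07. After median-ratio scaling their median was −0.75, with 30 of the 42 lower in both VavCre than in both control libraries and 8 higher. The hexokinases Hk2 and Hk3 fell by 1.39 and 1.20 log2 units and Gpi1 rose by 1.23, 3 of 24 glycolysis genes (1 higher and 2 lower adjusted over the list alone). Among 39 cytokine receptors Il10ra (log2 2.71) and Il6st (1.54) rose and Tnfrsf9 fell (−1.44), counts that did not move adjusted over the list alone. Among 36 chemokine receptor and homing genes, 2 rose and Ccr8 (−2.28) fell, with 4 higher and 2 lower adjusted over the list alone. Of 43 lineage transcription factors Irf4, Bcl11b and Id3 were among 5 that rose, and Ikzf2 fell (5 and 1 adjusted over the list alone). Of 26 BCL2 family and death receptor genes 5 rose, including Bok, Pmaip1, Bid and Bak1 (9 higher and 1 lower adjusted over the list alone). Of 25 myeloid markers Cybb, Prg2 and Clec10a rose (5 adjusted over the list alone), Clec10a having no reads in either control library. Il22 was the 1 called member among 5 AHR target genes, and Pf4 the 1 among 8 red cell and platelet genes (1 higher and 1 lower adjusted over the list alone for each). None of 19 stromal markers or 78 ribosomal protein genes was called over all genes or adjusted over the list alone. After median-ratio scaling Rgs2, Hk2, Hk3, Tnfrsf9 and Il22 still passed and the other genes called in these lists did not. In camera (limma) the immediate early, AHR target and cytokine receptor lists lay below other genes with adjusted p of 4.81e-05, 0.00313 and 0.0203, each with adjusted p = 0.42 with an estimated correlation. The transcription factor, homing, BCL2, glycolysis, myeloid, stromal, red cell and ribosomal lists were not called, with adjusted p of 0.659, 0.0946, 0.276, 0.223, 0.897, 0.112, 0.494 and 0.112.

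**Figure D3:**
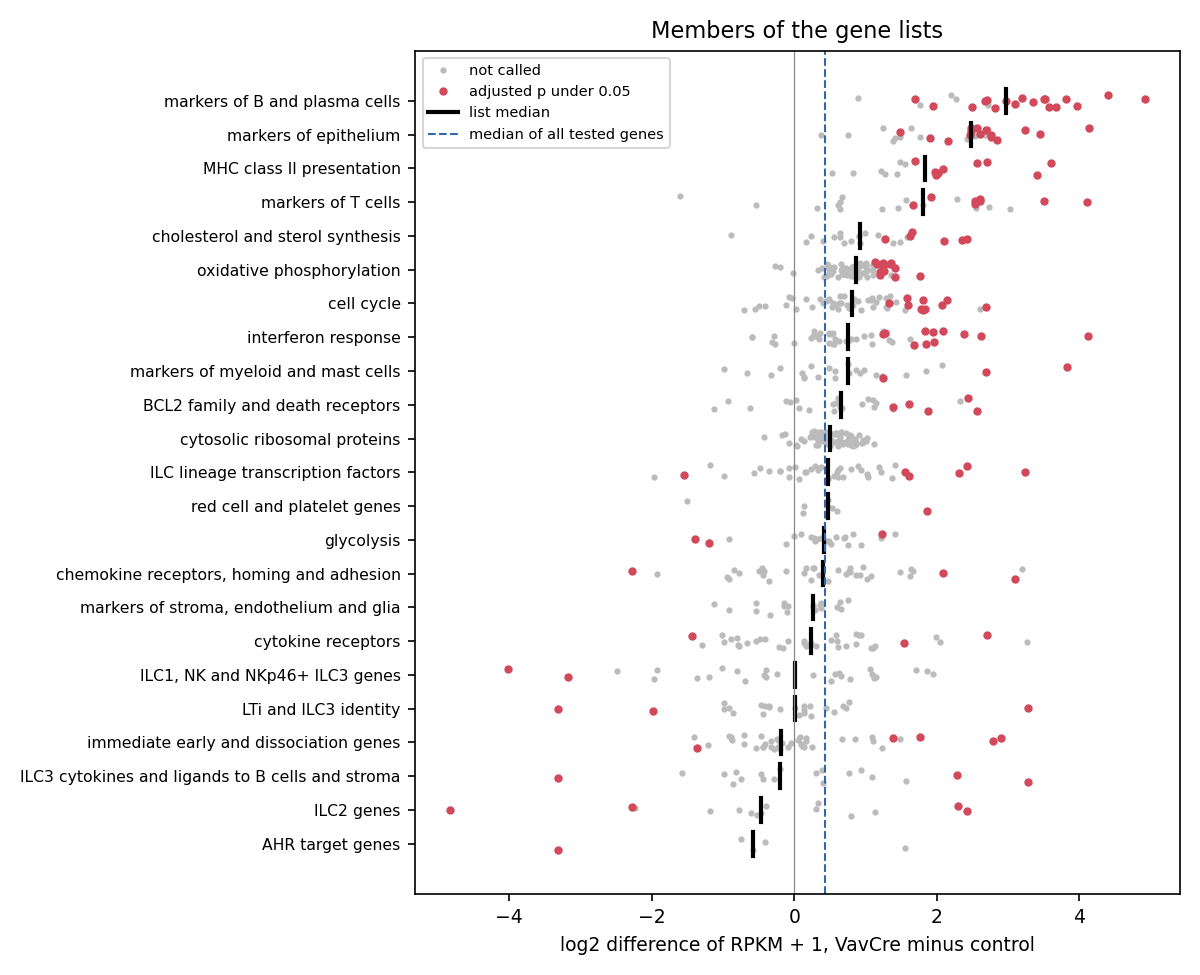
Log2 difference of RPKM + 1 (VavCre minus control) of each tested member of the gene lists, with called genes in red, uncalled genes in grey, a black bar for the list median and a dashed line for the median of all tested genes at 0.43. Among the 23 lists drawn, which leave out the sort gate genes, the medians of B and plasma cell markers lay furthest to the right and those of ILC2 and AHR target genes furthest to the left.

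Over the whole transcriptome, limma called 1278 of 14285 tested genes, 1180 higher and 98 lower in VavCre cells. With median-ratio scaling 144 were called, 82 higher and 62 lower, of which 82 and 59 were also called in the same direction on the deposited scale. Leaving out any 1 library left 0 genes called in limma on the deposited scale, with 3618 at an unadjusted p under 0.05 without control replicate 1, 3817 without control replicate 2, 2692 without VavCre replicate 1 and 2402 without VavCre replicate 2. The labels do not say whether the replicates came from separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of camera (limma) with its preset correlation compare list members with other genes and do not directly measure the spread between libraries.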

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

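TMM scaling and the combinations of median-ratio scaling with voom, the replicate block and left-out libraries were chosen after seeing the data. All 78 named genes that passed on the deposited scale kept their direction under each setting that tested them (75 with the stricter filter), and 26 still passed with median-ratio, 30 with upper-quartile and 27 with TMM scaling, 38 with limma-voom, 23 with limma-voom and median-ratio scaling, 0 in limma without a filter and 0 in limma on the deposited scale without any 1 library. Of uncalled named genes, Rora passed with limma-voom and median-ratio scaling and Csf2 with the stricter filter. The count of 1278 called genes (1180 higher, 98 lower) became 144 (82, 62) with median-ratio, 183 (117, 66) with upper-quartile and 161 (97, 64) with TMM scaling, 221 (185, 36) with limma-voom, 90 (27, 63) with limma-voom and median-ratio scaling and 263 (238, 25) against a fold of 1.5. A pseudocount of 0.1 gave 852 (780, 72) and the stricter filter 1720 (1587, 133). Without a filter limma called 0 genes, with 4335 at an unadjusted p under 0.05, and limma-voom with the filter called the 221 above. Leaving out 1 library gave 0 to 0 calls in limma on the deposited scale, with 2402 to 3817 genes at an unadjusted p under 0.05. With median-ratio scaling it gave 4 without control replicate 1, 82 (61, 21) without control replicate 2 and 0 without either VavCre replicate, with 1591 and 1685 genes at an unadjusted p under 0.05. Fewer samples then estimate the spread, and the lone sample is assumed to vary like the other group. The Gata3 level stayed uncalled under each setting, with log2 differences between −0.82 and −2.09. The 15 called lists became 0 with an estimated correlation in camera (limma), where 0 had an unadjusted p under 0.05, and 12 to 17 with a library left out. The myeloid list, uncalled with all libraries, lay above other genes without VavCre replicate 1 (0.99, adjusted p = 0.00396) and below without VavCre replicate 2 (−0.56, adjusted p = 0.0112), both in camera (limma). The ILC1 list lost its call without control replicate 2, the interferon list without VavCre replicate 2 and the cytokine receptor list without either. Uncalled lists gained a call without control replicate 1 (ribosomal, stromal and red cell genes) and without VavCre replicate 1 (homing genes). Without control replicate 1 and without control replicate 2 the log2 differences were 3.38 and 4.87 for Ifi27l2a, 2.05 and 3.34 for Ccnb2, 2.08 and 3.72 for Myc, 3.02 and 4.33 for Cd79a and 2.92 and 4.71 for Prg2, and without VavCre replicate 1 and without VavCre replicate 2 they were 3.18 and 4.45 for Prg2 and 1.62 and 2.94 for Tnfsf4. The cause of the other losses was not tested.

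Same-numbered replicates did not deviate together (correlation across genes −0.02), which gave no sign that the numbers pair the samples. With 2 libraries per genotype this cannot exclude pairing, and the labels do not say what the numbers mean. The replicate block gave 1014 calls (939, 75), and 25 (18, 7) with median-ratio scaling. Of the 78 named genes, 65 and 9 still passed, and Il22, Il17a and Cd4 were not among the 9 (adjusted p = 0.0871, 0.0741 and 0.0832 in limma). Gata3 stayed at −1.18.

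Among the named genes, signs turned only for uncalled ones. With median-ratio, upper-quartile, TMM, limma-voom with median-ratio and block with median-ratio scaling in that order, Tcf7 was at −0.14, −0.11, −0.13, −0.15 and −0.14, Cxcr5 and Il2ra both at −0.46, −0.43, −0.44, −0.47 and −0.46, Il23r at −0.37, −0.34, −0.35, −0.38 and −0.37 and Ahr at −0.36, −0.34, −0.35, −0.52 and −0.36. With a library left out, on either scale, the ranges were −0.33 to 1.37 for Ccr6, −0.70 to 2.38 for Klrb1c, −1.51 to 0.29 for Id2, −0.31 to 0.70 for Tcf7, −0.79 to 0.54 for Cxcr5, −1.05 to 0.11 for Ltb, −0.82 to 0.08 for Tnfsf13b, −0.15 to 0.71 for Tnfsf13, −1.78 to 0.35 for Il17f, −0.62 to 0.54 for Il23r, −0.66 to 0.40 for Il2ra and −0.51 to 0.17 for Ahr. Depth limits genes near the floor of 3 reads.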

Other observations

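All tests below but the pair on the median gene were chosen only after the result was seen. The comparison of genes in the next paragraph was chosen then too, and Cd3d, Trdc, Slc29a3 and Igha were named then. The same holds for the bound used as spread for the median gene, and for the narrowing of the ILC2 test to Arg1 and of the dilution test to Il22 and Cd4.

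Il17a stood at 121 and 122 RPKM in VavCre replicates 1 and 2, where Cd3g stood at 203 and 53.1, Cd3d at 62.0 and 2.35 and Trdc, the constant gene of the δ T cell receptor, at 63.9 and 2.42 RPKM. Trgc4 stood at 71.2 and 33.8, Cd8b1 at 9.90 and 4.24 and Cd247 at 9.51 and 10.3 RPKM. Cd3d and Trdc were far apart between the VavCre libraries and Cd247 was not. These values therefore cannot tell whether LTi cells or T cells made the Il17a reads, which was not tested. Il17f was at 60.1 and 120.9 RPKM in the same libraries and did not pass the test. Reads assigned to Slc29a3, which could not be told from repeat reads or reads with several positions here, made up 17.2% and 27.1% of the reads of the control libraries and 7.87% and 7.61% of those of the VavCre libraries, with 95% Wilson intervals of 17.2 to 17.2%, 27.1 to 27.1%, 7.86 to 7.88% and 7.60 to 7.62%. Igha, the constant gene of IgA, took 0.374% and 1.05% in control (0.371 to 0.377% and 1.05 to 1.06%) and 6.89% and 2.47% in VavCre libraries (6.88 to 6.90% and 2.46 to 2.47%), and it did not pass limma's test (adjusted p = 0.0662). Of 228 tested genes of the immunoglobulin loci 83 rose on the deposited scale, and 30 rose on both scales.

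Il22, Arg1 and other genes of the innate lymphoid lists were lower in the VavCre libraries. Dilution of LTi RNA by RNA of other cells would lower alike the genes that only LTi cells make. After median-ratio scaling the median of the 25 tested LTi and ILC3 identity genes was −0.57 (SD 1.15), 3.33 above Il22 and 1.97 above Cd4. Il22 and Cd4 were picked as the called lower members of that same list. They were therefore bound to lie below its median, so the sign of the gap is no evidence, but its size was not fixed. Dilution strong enough for the Il22 fall of −3.90 (SE 0.41) would have lowered as far the genes that only LTi cells make. The list median of −0.57 argues against dilution alone for Il22, so far as its members are made only by LTi cells. The smaller gap of Cd4 cannot tell dilution apart from other causes. ILC2 in the control sort as the source of Arg1 would bring their other transcripts. The summed RPKM of Il1rl1, Il5, Il13, Il17rb and Klrg1 came to at most 1.51% of that of Arg1 in the control libraries. The sort left out KLRG1+ cells, so the low level of Klrg1 is no separate evidence. ILC2 with little of these transcripts were not tested. Dilution stays open for Cd4 and as a part of the Il22 fall, and was not tested for the genes of the other lists. An effect of the genotype on LTi cells and a change in the kinds of LTi cells sorted stay open and were not tested.

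B cell, plasma cell and epithelial genes were higher in the VavCre libraries, although the sort left out lineage-positive cells. RNA of such cells in the VavCre sort cannot be told apart from other causes, since the 86.0% of 50 tested markers that were higher in both VavCre than in both control libraries after median-ratio scaling (29.8% of all genes, 16.7% by chance) restate the rises, with Ighm at 850 and Epcam at 149 RPKM. A lower LTi share could raise all other cell types alike. The list medians after median-ratio scaling were 2.50 for B and plasma cells, 1.91 for epithelium, 1.33 for T cells, 0.37 for myeloid cells and −0.17 for stroma. The highest and lowest, picked after the values were seen, lay 2.68 apart, which argues against an equal rise on this scale. The log2(RPKM + 1) scale understates changes of low genes, however. Whether B cell RNA alone made the class II rise cannot be told apart, since Ciita, H2-Ob and H2-DMb2 rose by a mean of 2.54 and Pax5 by 2.56 in the same libraries. Whether the genotype changed the cells around the LTi cells was not tested.

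The median gene was 0.43 log2 units higher in the VavCre libraries on the deposited scale. A few genes taking most of the counts may account for part, as the difference was 0.25 (0.21 to 0.29 over library pairs) with the 20 most read genes left out of the totals, but this lies on the bound set in advance and so cannot be told apart. Deeper sequencing of the VavCre libraries, lifting genes near the detection limit, cannot be told apart either, since the difference was 0.36 in the 1429 genes with the highest mean, past the bound of 0.25 set in advance, but 0.13 to 0.52 over library pairs. A change in the RNA content of the cells with genotype stays open and was not tested.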
